A study of Homo sapiens with 4 samples.

How the data were processed

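RNA from MDA-MB-231 and MDA-MB-231-P3 cells was sequenced by the submitters as strand-specific paired-end libraries from the mRNA fraction, per the labels' protocols. The submitters' processing notes name HISAT2, StringTie and the hg19 genome, and their versions are not given in the sources used here. Per the labels' protocols, the authors aligned the reads with HISAT2 and normalized them to FPKM, and the deposited values are FPKM per lncRNA isoform. The lncRNA annotation and the step that assigned reads to isoforms are not given in the sources used here. Values of each per-sample file equalled those of the series table in all 4 libraries, so 1 set of values was analysed. Depth per library was unknown: FPKM values are not counts, and the low values extended continuously to magnitudes far below a single read, so read numbers could not be recovered and no interval for counting error was given. A value at or near 0 in this table can be a failed estimate of an isoform's share, so such features are described as listed at or near 0, with the value of each library.

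Libraries were grouped by the cell line in the labels, 2 per line. Features with a mean FPKM over the 4 libraries of at least 0.5 were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, subline minus parent, no block). P-values were adjusted with the Benjamini-Hochberg method over all features tested, with a threshold of 0.05. Isoform rows were the planned level, and values summed per gene were the other level set for the count of changed features. The repeat of every setting and of the list tests on summed values was added after the data were examined. Gene lists were fixed before the data were examined: 25 lists, of which 8 had rows in this lncRNA table. In the isoform test, the isoform of highest mean FPKM stood for its gene. Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01, two-sided, adjusted over the lists tested), with an estimated correlation and fry as alternatives, and members were also adjusted over the list alone.

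The design, the lists, the other settings and the rule for named genes were set before the data were examined. The rule took the uc003xsl.1 and NF-κB/IL8 genes of the title where listed, up to 10 called features per direction by fold change, features of smallest p up to 4 per direction where fewer passed, up to 3 called members or otherwise the 2 most abundant members of each list with at least 3 tested members, and the 3 most abundant features. Levels of members are given as sums per gene. The further members SNHG1, SNHG7, SNHG8, ZFAS1, GAS5, CYTOR, MIR100HG and MIR3142HG and the genes drawn in the plots were chosen after their values were seen. Y-linked genes and XIST were left out, and 1 of the 4 summed genes that passed the test, counted among the 2 higher ones, is not reported here.

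The other settings were pseudocounts of 0.1 and 1, no filter or a minimum of 1 FPKM, quantile normalization, centring on the median log ratio, eBayes without the trend, the replicate number as a block, calls that also changed by at least 1 on the log2 scale, and leaving out each library in turn. Coordinates came from GENCODE release 44 lifted to GRCh37, the sequence of hg19, and 686 of the 6444 tested genes had their own symbol in it. Explanations were tested with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The tests were tested on simulated data with 200 changed features among 8432 isoforms or 6444 genes. Of features changed by 1, 2, 4 and 6 on the log2 scale, 0%, 0%, 32% and 74% of isoforms and 0%, 4%, 74% and 78% of genes were called, along with 4 unchanged isoforms and 2 unchanged genes. These rates hold for 200 changed features, and fewer true changes would tighten the adjusted threshold.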

Results

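Long noncoding RNA (lncRNA) abundance was measured by strand-specific sequencing in MDA-MB-231, a human triple-negative breast cancer cell line, and in MDA-MB-231-P3, a subline derived from it. Per the labels' protocols, the subline was obtained by repeated tail vein injection of the cells into mice, recovery of the cells that had grown in the lung, and expansion in culture. Each line was represented by 2 libraries, 4 in all. The labels did not say whether the 2 libraries of a line came from separate cultures. The p-values of single lncRNAs therefore measured only the spread between these libraries, which may be technical. The camera p-values of lists with a preset correlation compared the members with the other lncRNAs. They took lncRNAs and not libraries as the units. The table listed 104786 lncRNA isoforms, which belonged to 46902 lncRNA genes, in FPKM, a measure of fragments relative to transcript length and to the mapped fragments of the library. Read depth was unknown, because the values were FPKM and no read counts were used here.

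The parental libraries listed 52357 and 50931 isoforms above 0, and the MDA-MB-231-P3 libraries listed 57477 and 55862. Genes with a summed FPKM of at least 1 numbered 3916 and 3915 in the parental libraries and 4343 and 4223 in the MDA-MB-231-P3 libraries. The FPKM of all listed isoforms summed to 460282 and 500086 in the parental libraries and to 351135 and 372689 in the MDA-MB-231-P3 libraries. The 10 most abundant isoforms of each library held 72.7% and 67.7% of this sum in the parental line and 69.4% and 67.9% in the subline. The 3 most abundant isoforms over all libraries were lnc-EPN2-3:3, lnc-ARHGEF39-1:4 and SNHG3:6. For lnc-ARHGEF39-1:4 the mean was 70459 ± 24096 FPKM (SD, n = 2) in MDA-MB-231 and 57255 ± 12603 FPKM (SD, n = 2) in MDA-MB-231-P3. For SNHG3:6 it was 35053 ± 14771 and 36101 ± 6237 FPKM (SD, n = 2 each). The isoform lnc-EPN2-3:3 was listed at 108784 and 34625 FPKM in the parental libraries and at 25383 and 10174 FPKM in the subline. Across isoforms, Pearson's r of log2(FPKM + 0.5) was 0.766 between the parental libraries, 0.788 between the MDA-MB-231-P3 libraries and 0.708 to 0.735 between libraries of different lines. Across summed genes it was 0.836 and 0.846 within the lines and 0.773 to 0.806 between them. Isoforms and genes are not independent replicates, so these values carry no p-value.

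The comparison of MDA-MB-231-P3 with MDA-MB-231 asked which lncRNAs differ between the lung-selected subline and its parent. With isoform values summed per gene, 4 lncRNA genes passed the test, 2 higher and 2 lower in the subline, and each was low or listed near 0 in one of the lines. PCED1B-AS1, an antisense lncRNA of the PCED1B locus, was 138-fold higher in the subline, at 60.7 ± 6.10 FPKM (SD, n = 2) against 0.440 ± 0.109 FPKM (SD, n = 2) in the parent. In the opposite direction, lnc-P4HTM-2 was listed at 34.0 and 26.7 FPKM in the parent and at 0.00259 and 0.000116 FPKM in the subline, and lnc-SPRYD4-1 was listed at 21.5 and 33.0 FPKM in the parent and at near 0 and 0.0327 FPKM in the subline. A name of the form lnc-GENE-number denotes a neighbouring gene and not the lncRNA's function.

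On the log2(FPKM + 0.5) scale, which understates the change of low values, PCED1B-AS1 differed by 6.02 (SE 0.26, limma adjusted p = 0.0399). The difference was -5.94 for lnc-P4HTM-2 (SE 0.27, limma adjusted p = 0.0399) and -5.72 for lnc-SPRYD4-1 (SE 0.32, limma adjusted p = 0.0491). PCED1B-AS1 is annotated as a lncRNA on the minus strand of chromosome 12 between 47599676 and 47610270 (hg19). Among its isoforms, PCED1B-AS1:12 was listed at 12.4 and 13.3 FPKM in the subline and near 0 in both parental libraries. Neither lnc-P4HTM-2 nor lnc-SPRYD4-1 has a symbol of its own in the annotation used here, so no coordinates were assigned to them.

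At the level of single isoforms, the level at which the values were deposited, limma called 0 of 8432 tested isoforms higher and 0 lower, and the smallest adjusted p was 0.0905. An unadjusted p under 0.05 was reached by 1124 isoforms, 664 of them higher and 460 lower in the subline, where chance alone gives 422. Of the 6444 summed genes, 978 reached an unadjusted p under 0.05, 612 higher and 366 lower, where chance gives 322. Both libraries of one line lay above both of the other for 48% of isoforms and for 50.3% of genes, and chance gives 33.3%. The 4 calls on summed genes fell to 0 with a pseudocount of 1, without the filter on low values or without the intensity trend, and to 2 with quantile normalization. They were also lost when any one of the 4 libraries was left out. Such a fit leaves 1 library in a line, so this loss decides little. The log2 difference of lnc-P4HTM-2 was then -6.11 to -5.76. In data simulated with the fitted spread, 74% of genes changed by 4 on the log2 scale were called. Of those changed by 2 and by 1, 4% and 0% were called, and 2 unchanged genes were called as well. The simulated genes were independent and had no floor near 0 FPKM. The simulation held 200 changed genes, and many true changes loosen the adjusted threshold for each gene. The rate of 74% may therefore be too high for these data. For example, lnc-ASAP1-7, with a log2 difference of 4.13, was not called (limma adjusted p = 0.0623). Each of the 4 called genes was low or near 0 in 1 of the lines, so these rates may not describe them.

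**Figure D1:**
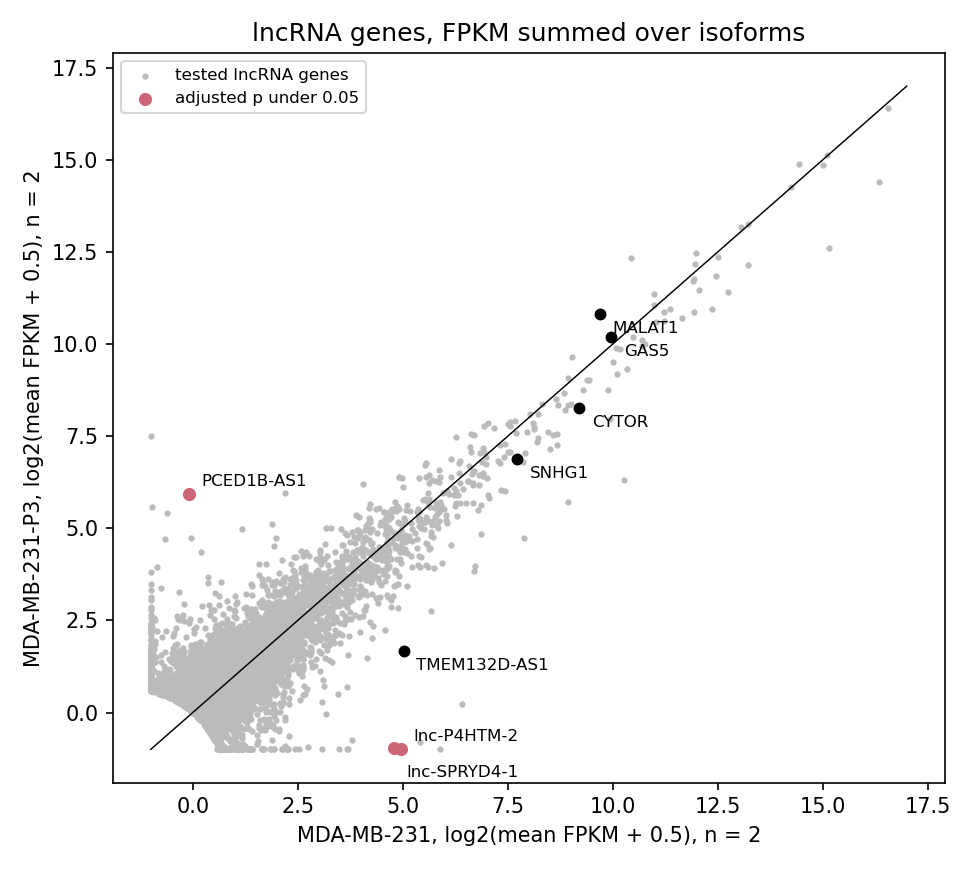
Mean FPKM of each tested lncRNA gene in MDA-MB-231 (horizontal axis) and MDA-MB-231-P3 (vertical axis), both as log2(mean FPKM + 0.5), n = 2 libraries per line; the line marks equal values. The coloured genes, PCED1B-AS1, lnc-P4HTM-2 and lnc-SPRYD4-1, had an adjusted p under 0.05 and lie far from the line, PCED1B-AS1 at 0.440 against 60.7 FPKM, and the genes in black did not pass.

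Other lncRNAs of smallest p did not pass the test. TMEM132D-AS1, an antisense lncRNA of the gene for a transmembrane protein, had 31.9 ± 2.33 FPKM (SD, n = 2) in the parent and 2.68 ± 0.0863 FPKM (SD, n = 2) in the subline, a log2 difference of -3.35 (SE 0.25, limma adjusted p = 0.0798). It lies on the plus strand of chromosome 12 between 129594174 and 129597839 (hg19). The genes lnc-ASAP1-7, at 7.73 and 8.83 FPKM in the subline (limma adjusted p = 0.0623), and lnc-ISM2-1, at 5.72 and 7.10 FPKM in the subline (limma adjusted p = 0.0798), were listed near 0 in both parental libraries. The gene lnc-TOE1-1 was listed at 4.06 and 4.50 FPKM in the parent and near 0 in both subline libraries (limma adjusted p = 0.109). Among single isoforms, lnc-SLC35E3-8:1 was listed at 31.7 and 30.7 FPKM in the subline and near 0 in both parental libraries (limma adjusted p = 0.0905). The isoform lnc-CCDC28A-1:3 was listed at 5.01 and 6.29 FPKM in the parent and at 0.00745 and 0.00520 FPKM in the subline (limma adjusted p = 0.111). The isoform lnc-DNTTIP2-1:5 was listed at 16.1 and 8.90 FPKM in the parent and near 0 in both subline libraries (limma adjusted p = 0.111).

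**Figure D2:**
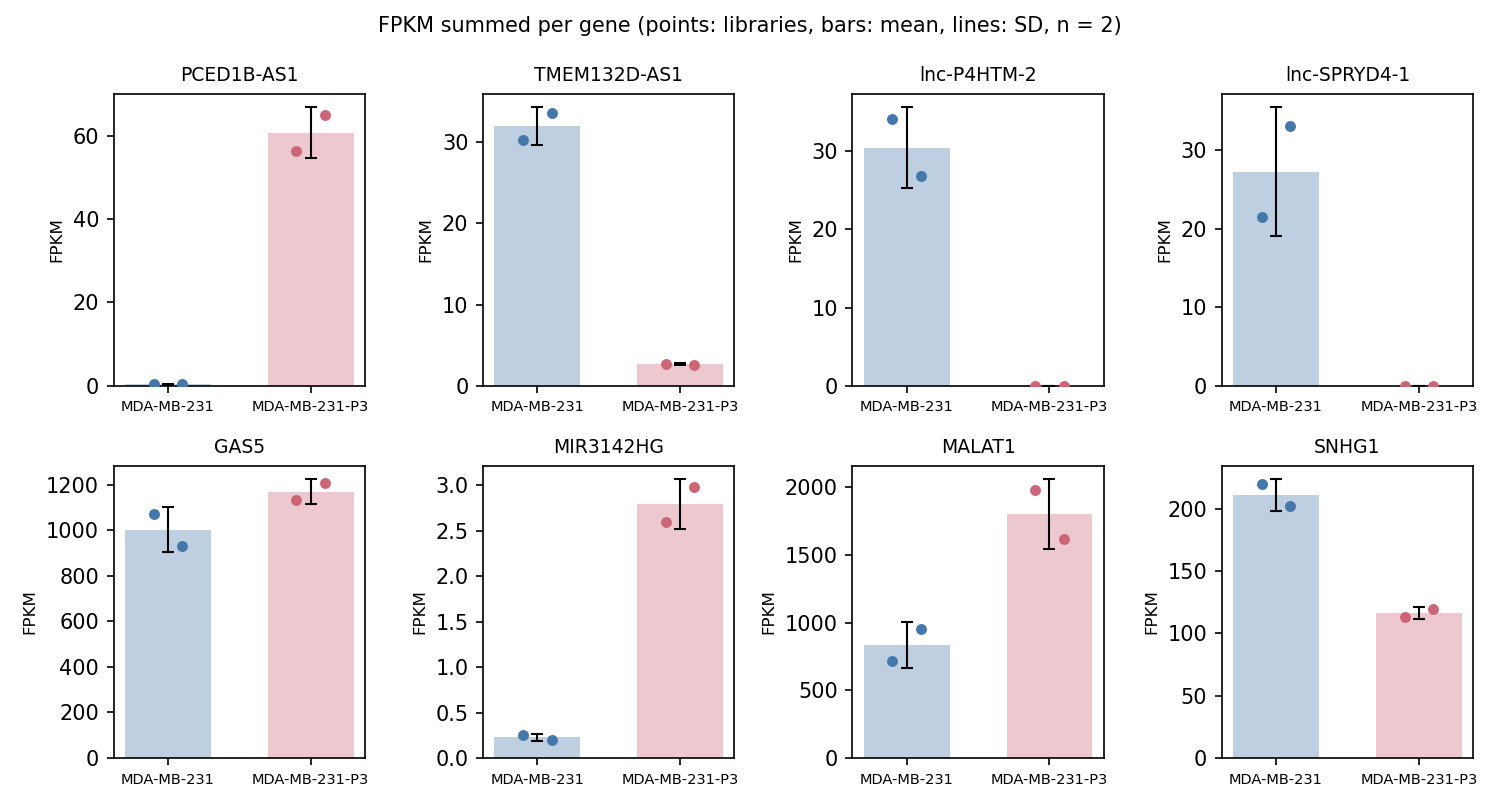
FPKM summed per gene for 8 lncRNAs in MDA-MB-231 and MDA-MB-231-P3: points are libraries, bars the mean of n = 2 and lines the SD, with the vertical axis in FPKM from 0. PCED1B-AS1 stands at 60.7 ± 6.10 FPKM in the subline against 0.440 ± 0.109 FPKM in the parent, and SNHG1 at 116 ± 4.90 against 211 ± 12.6 FPKM.

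LncRNAs that host small nucleolar RNAs (snoRNAs) in their introns were lower as a group in the subline. After adjustment over the lists, camera called this with a preset correlation and not with an estimated one. Of 22 tested hosts, represented by their most abundant isoform, 18 had a negative log2 difference and 4 a positive one, with a median of -0.71 (limma camera adjusted p = 4.02e-05 with a preset correlation, adjusted p = 0.159 with an estimated correlation). With values summed per gene, 19 of 22 were negative, with a median of -0.54 (camera adjusted p = 6.24e-06 with a preset correlation, adjusted p = 0.197 with an estimated correlation). The estimated correlations were -0.0275 for isoforms and -0.0363 for summed genes, below the preset 0.01. The larger p therefore did not come from a higher correlation among the hosts. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries. With the preset one it takes them from the many lncRNAs, so the 2 results differ in their units. Unadjusted, the camera p with an estimated correlation was 0.0398 for isoforms and 0.0329 for summed genes. Fry gave an adjusted p of 0.0421 and 0.0469. With quantile normalization the median was -0.40 for isoforms (preset camera adjusted p = 0.0188) and -0.33 for summed genes (preset camera adjusted p = 0.0464). No single host passed over all features tested or adjusted over the list alone, where the smallest adjusted p was 0.0841 for isoforms and 0.119 for summed genes. Both subline libraries lay below both parental libraries for 17 of the 22 summed hosts and above them for 1, where chance gives 16.7% in each direction. Of all 6444 tested genes, 1379 lay below and 1861 above in this way. The hosts were measured in the same libraries and are not independent draws.

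Among the hosts, SNHG1 on chromosome 11 had 211 ± 12.6 FPKM in the parent and 116 ± 4.90 FPKM in the subline (SD, n = 2 each). SNHG7 had 130 ± 6.46 and 59.3 ± 2.74 FPKM, SNHG8 had 1287 ± 283 and 639 ± 13.4 FPKM, and ZFAS1 had 1093 ± 13.3 and 581 ± 38.0 FPKM (SD, n = 2 each). GAS5, a growth-arrest-associated snoRNA host, had 1002 ± 99.4 FPKM in the parent and 1169 ± 53.1 FPKM in the subline. The most abundant hosts varied between libraries of the same line: SNHG10 had 2628 ± 1185 FPKM in the parent and 1989 ± 1004 FPKM in the subline, and the sign of the differences of SNHG10 and of SNHG3 changed when single libraries were left out. The median log2 difference of all summed genes was 0.09 as deposited and -0.03 after quantile normalization.

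**Figure D3:**
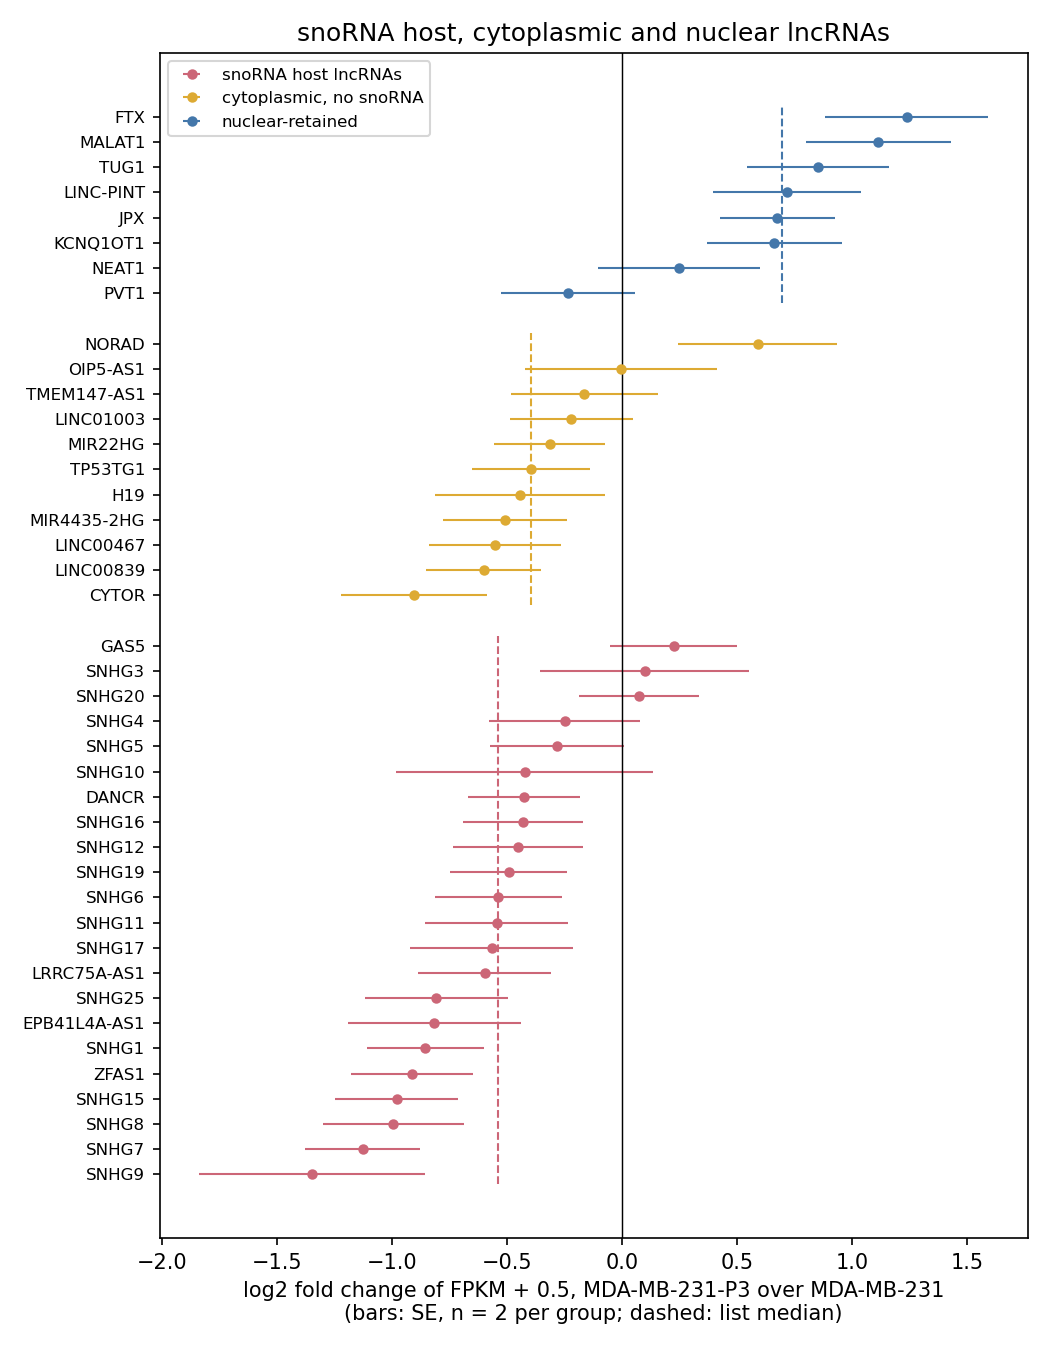
Log2 difference of FPKM + 0.5 between MDA-MB-231-P3 and MDA-MB-231, summed per gene, for snoRNA hosts, cytoplasmic lncRNAs without a snoRNA and nuclear-retained lncRNAs; points are genes, bars the SE (n = 2 per line) and dashed lines the list medians. The medians were -0.54 for 22 snoRNA hosts, -0.40 for 11 cytoplasmic and 0.70 for 8 nuclear-retained lncRNAs.

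No other fixed list passed. The inflammation-linked lncRNAs, 7 tested, had a median log2 difference of 0.54 for isoforms (camera adjusted p = 0.528) and 0.25 for summed genes (camera adjusted p = 0.535), with 0 members called over all features. Adjusted over the list alone, 1 member was called higher: MIR3142HG, the host of miR-3142 and miR-146a, had 0.230 ± 0.0386 FPKM in the parent and 2.79 ± 0.272 FPKM in the subline (SD, n = 2 each), a log2 difference of 2.17 (SE 0.28, limma adjusted p = 0.00686 over the list alone and 0.213 over all genes). The call over the list alone was lost whichever library was left out, but such a fit leaves 1 library in a line, so this loss decides little. MIR3142HG lies on chromosome 5 between 159865601 and 159914433 (hg19). The most abundant members were NEAT1, at 120 ± 28.9 and 143 ± 39.3 FPKM, and LINC-PINT, at 23.3 ± 6.75 and 38.0 ± 4.01 FPKM (SD, n = 2 each).

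The microRNA hosts included MIR3142HG as the 1 member called over the list alone, with a limma adjusted p of 0.0173 for its isoform and 0.0137 summed. This call too was lost whichever library was left out, which decides as little. Over all features, 0 of 12 tested isoforms and 0 of 14 summed genes were called. The list median was 0.03 for isoforms (camera adjusted p = 0.956, direction down) and 0.38 for summed genes (camera adjusted p = 0.332). MIR4435-2HG had 189 ± 4.99 FPKM in the parent and 133 ± 19.7 FPKM in the subline, and MIR17HG, a host of a polycistronic microRNA cluster, had 32.0 ± 2.30 and 38.1 ± 4.86 FPKM (SD, n = 2 each). Values of MIR4435-2HG and CYTOR are uncertain, because these genes share near-identical sequence.

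Metastasis-linked lncRNAs went both ways. Of 12 tested isoforms 7 were positive and 5 negative, with a median of 0.03 (camera adjusted p = 0.956, direction down), and of 14 summed genes 6 were positive and 8 negative, with a median of -0.24 (camera adjusted p = 0.611). None was called over all features or adjusted over the list alone, where the smallest adjusted p was 0.252 for isoforms and 0.107 for summed genes. MALAT1, a nuclear lncRNA, had 834 ± 166 FPKM in the parent and 1799 ± 258 FPKM in the subline, a log2 difference of 1.11 (SE 0.32, limma adjusted p = 0.282). CYTOR, uncertain for the reason above, had 588 ± 158 and 308 ± 4.40 FPKM (limma adjusted p = 0.313), and MIR100HG had 23.2 ± 0.594 and 42.7 ± 2.16 FPKM (SD, n = 2 each).

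Hypoxia-linked lncRNAs had 7 summed members tested, with a median of -0.10 and a mean of 0.21 (camera adjusted p = 0.931, direction up), and MALAT1 and NEAT1 were the most abundant. The p53-linked lncRNAs had 5 summed members tested, with a median of 0.25 (camera adjusted p = 0.992), NEAT1 and PVT1 being the most abundant, and PVT1 had 54.4 ± 5.62 and 46.5 ± 9.60 FPKM. As isoforms, 4 members of each of these lists were tested, too few for the list test, and the medians were 0.43 and 0.36. The imprinted lncRNAs had 4 summed members tested, with a median of -0.17: GNAS-AS1 had 3.79 ± 0.185 and 1.63 ± 0.210 FPKM (limma adjusted p = 0.0579 over the list alone) and DLGAP2-AS1 had 17.8 ± 1.50 and 19.5 ± 5.36 FPKM (SD, n = 2 each). Of the HOX cluster lncRNAs, only HAGLR passed the filter, at 3.46 ± 0.746 and 2.79 ± 0.467 FPKM (SD, n = 2 each). The other 17 of the 25 fixed lists held protein-coding genes and had 0 rows.

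The series title names uc003xsl.1 and the NF-κB/IL8 axis. No row carried the name uc003xsl.1, and none carried the names CXCL8, IL8, NKRF, RELA or NFKB1, so these are not analysed here. The search was by name only, so the lncRNA uc003xsl.1 could be listed under another name. Among lncRNAs named for neighbouring genes, lnc-CXCL8-1 was listed at 0 in all 4 libraries and lnc-NKRF-2 near 0 in all 4. The lncRNA lnc-NFKB1-6 was listed at 0.787 FPKM in parental library 1 and at 0 in the other 3 libraries, and none of these lncRNAs reached the mean FPKM of 0.5 needed for testing.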

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

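The repeats of the tests on values summed per gene were chosen after the data were examined, except the count of changed features itself, which was planned. The count of 0 changed isoforms was the same under every setting chosen beforehand except 2: it was 6 with a minimum mean FPKM of 1, and 4 with values summed per gene. The 4 summed genes were called again with a pseudocount of 0.1, a minimum of 1 FPKM or centring. The count was 0 with a pseudocount of 1, without the filter (28292 genes tested) or without the trend, and 2 with quantile normalization. The calls were also lost whichever library was left out. Each of the 4 differences kept its direction in all of these settings. Isoforms with an unadjusted p under 0.05 numbered 3434 without the filter, 742 with a minimum of 1 FPKM, where more and fewer isoforms were tested, and 746 to 1113 without single libraries, against 1124. Summed genes numbered 2500 without the filter and 564 to 906 without single libraries, against 978, and leaving out MDA-MB-231-P3 replicate 1 gave the lowest of both. The snoRNA hosts kept their direction and their call in every alternative but camera with an estimated correlation, which left medians of -0.71 for isoforms and -0.54 for summed genes uncalled. Without single libraries their medians were -0.72 to -0.50 and -0.61 to -0.47. Medians of lists that were not called changed sign: metastasis-linked isoforms to -0.019 with quantile normalization and -0.071 to 0.11 without single libraries, microRNA host isoforms to -0.10 to 0.13, and, on sums, hypoxia-linked to -0.046 to 0.14, inflammation-linked to -0.035 to 0.49, metastasis-linked to -0.43 to 0.015 and p53-linked to -0.31 to 0.49. Single genes that changed sign, none of them called, were DLGAP2-AS1 (-0.18 to 0.38), NEAT1 (-0.035 to 0.53), SNHG10 (-0.96 to 0.12) and SNHG3 (-0.34 to 0.54). In repeats over its lists alone, chosen after the data were examined, MIR3142HG was lost as an isoform whichever library was left out (adjusted p of 0.0603 to 0.102 for inflammation-linked and 0.154 to 0.207 for microRNA hosts), and among microRNA host isoforms with a minimum of 1 FPKM (0.0619). Another member was called in 3 of these repeats: inflammation-linked isoforms without MDA-MB-231 replicate 1, and summed microRNA hosts without the filter or without the trend. The cause of these changes was not tested. A fit without 1 library assumes that the lone library of its line varies like the other line. It also has fewer degrees of freedom, so a call can be lost in it with little change in the difference. No row carried the name of a gene in the title and the per-sample files held the same values, so those alternatives gave no value.

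With the replicate number as a block, 0 isoforms and 0 summed genes were called, against 0 and 4, and 941 isoforms and 887 genes had an unadjusted p under 0.05. Same-numbered libraries shared only a number: their deviations correlated at 0.0474 across isoforms and 0.0777 across genes. The block changed no call of a list, and MIR3142HG kept its calls over its lists alone (adjusted p of 0.0187 to 0.0414); other lists were not adjusted alone under it. Depth was unknown, so it could not be weighed.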

Other observations

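The lists of nuclear-retained and cytoplasmic lncRNAs, the tests on them, the chance test of chromosome regions, the repeats of the window test with minimums other than 10, the test of lncRNAs next to NF-κB targets and 6 of the 7 trend fits below were chosen after results were seen, and all use values summed per gene. The minimum of 10 in the window test itself departed from the 20 set for regions.

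Nuclear-retained lncRNAs were mostly higher in MDA-MB-231-P3: 7 of 8 had a positive log2 difference, with a median of 0.70 (bootstrap SE 0.161), among them TUG1, typed as protein-coding in the annotation used here, at 17.7 ± 4.89 and 31.8 ± 1.95 FPKM (SD, n = 2 each), PVT1 being the exception. Cytoplasmic lncRNAs that host no snoRNA were mostly lower: 10 of 11 were negative, 1 of them, OIP5-AS1, at about 0 (28.7 ± 8.45 and 29.1 ± 11.5 FPKM, SD, n = 2 each), and among the others LINC00839 at 9.44 ± 0.381 and 6.05 ± 0.483 FPKM (SD, n = 2 each), with NORAD the exception at 144 ± 49.8 and 211 ± 2.70 FPKM. CYTOR and MIR4435-2HG, which share near-identical sequence, are counted as 2 of the 10 and are not independent. With quantile normalization the medians were 0.71 and -0.33, with 9 of 11 cytoplasmic lncRNAs negative, and without MDA-MB-231 replicate 1 the cytoplasmic median was -0.30, with 8 of 11 negative. None of these genes passed limma's test over all genes. The bootstrap of list medians, here and below, resampled the genes of a list and not the libraries. Its SE treats genes measured in the same libraries as independent. The nuclear-retained and cytoplasmic lists were written when the values of MALAT1, NEAT1, KCNQ1OT1, CYTOR and H19 had already been seen. TUG1, PVT1, LINC-PINT, MIR4435-2HG, TP53TG1 and MIR22HG also belonged to the fixed lists, so their values may have been seen too. These lists are therefore not an independent test.

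The first pattern weighed was the lower level of snoRNA hosts (median -0.54, bootstrap SE 0.0934). Abundance alone is argued against as the whole cause only as far as the match on mean expression holds. Of 10000 random lists matched on it, 0.59% had a median as low, and the matched lists had a median of -0.17. The match was coarse for the most abundant hosts, because few other genes reach their level. A cubic trend with mean expression alone, among the later fits below, left a median of -0.262 (bootstrap SE 0.0895). GC content and abundance together stay open: after the planned cubic trend with both was removed, fitted on all 687 genes with a sequence, the median was -0.126 (bootstrap SE 0.0946), within 2 standard errors of 0, although 17 of the 31 most abundant genes in that fit were hosts themselves. In 6 further fits tried after that value was seen (GC content alone, mean expression alone, or both, partly fitted outside the list) it was -0.508 to -0.239 and more than 2 standard errors below 0 in each, among them -0.296 (SE 0.114) for the same trend fitted outside the list and -0.239 (SE 0.0789) for the smallest, so only the planned fit met its bound and how much of the pattern the trend takes up depends on the fit. A lower share of cytoplasmic RNA in the MDA-MB-231-P3 libraries also stays open and may contribute, since cytoplasmic lncRNAs without a snoRNA had a median of -0.40 (bootstrap SE 0.11) and nuclear-retained ones one above 0, while a change in the selected subline itself was not tested apart from these.

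The second pattern was a difference between chromosome regions of 20 Mb with at least 20 genes: the SD of region medians was 0.219 over 127 regions and 5473 genes placed by their own or a neighbouring gene's symbol. Chance placement is argued against, since 0.0001 of 10000 random reassignments gave a spread as large (random median 0.15), the smallest share they can give. Regional GC content is argued against as the whole cause only as far as the trend captured it. After a joint trend with 100-kb GC content and mean expression was removed, the spread was 0.18 against 0.139 and the share was again 0.0001. Only 686 of the 6444 tested genes had their own symbol, so most were given the GC content at a neighbouring gene. The GC content of the transcripts was not removed, so part of a GC effect may remain. Shared transcription or reads of neighbouring lncRNAs are argued against as the whole cause, since with 1 gene per 1-Mb window the spread was 0.29 against 0.249 and the share was 0.0036 in regions of at least 10 genes, and 0.0005 to 0.005 with minimums of 5 to 18, while the minimum of 20 used above gave 0.997 (spread 0.000768 against 0.14) on the only 2 regions it leaves, 20 windows being the most a region can hold. GC content and shared neighbours were not removed together, so their combination stays open. The spread between libraries of the same line was not computed, so whether the pattern is particular to the lines is not known. A difference between the lines themselves stays open as untested. The lowest median was -0.367 on chromosome 9 from 120 to 140 Mb and the highest 0.588 on chromosome 5 from 40 to 60 Mb. These medians were not corrected for GC content, which was 52.2% and 39.5% there. Across genes, the log2 difference correlated with 100-kb GC content at Spearman's rho of -0.193.

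The title's NF-κB axis prompted a test of 6 lncRNAs named for neighbouring NF-κB target genes. Their median log2 difference was 0.34 and the unadjusted camera p was 0.873 with a preset correlation, which with so few members decides nothing. The lncRNA lnc-IL6-3 was listed at 3.44 and 2.92 FPKM in the parent and at 1.54 and 1.35 FPKM in the subline, and lnc-CXCL2-1 at 5.48 and 7.49 FPKM in the parent and at 9.15 and 8.49 FPKM in the subline.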
